A study of Mus musculus with 24 samples.

How the data were processed

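RNA was measured by sequencing of poly-A selected, stranded libraries from the sciatic nerve of wild-type C57BL/6 mice aged 5, 18, 21 and 24 months. Per the labels' protocols, RNA was extracted with a PureLink kit and libraries were made with the Illumina TruSeq Stranded mRNA kit. The series holds 24 libraries, and the labels mark 2 of them as excluded from analysis: 18 months replicate 5 for a low RNA integrity number and 24 months replicate 4 for low mapping. The 22 libraries in use were 6 at 5 months, 5 at 18 months, 6 at 21 months and 5 at 24 months, and the series' design text counts them as separate mice. The labels name 5 months as the control age. They give no sex, sequencing batch, date or time of day of collection.

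Raw counts per gene symbol were deposited for all 24 libraries. Per the submitters' processing notes, reads were converted with bcl2fastq 2.17, aligned with STAR 2.5.2b to build mm10 and counted with featureCounts 1.5.0-p3, with DESeq2 1.34.0 named for normalization. The notes give no gene annotation, strand setting or multi-mapping rule, so genes that share sequence with a close copy, and antisense or overlapping genes, are uncertain in these counts. The second deposited table, a normalized signal made by the authors, held 15930 genes for the 22 libraries. Each column equalled the raw counts divided by 1 factor per library, and at least 99.9% of the values in each column gave back the raw counts within 0.01 count. These factors equalled median-of-ratios size factors, from 0.508 to 1.77. All genes in that table had at least 10 counts in at least 4 libraries. The normalized signal was not used for any test. In the raw table of 23420 entries, 27 symbols had been turned into spreadsheet date numbers. They held 0.162% to 0.288% of a library's counts and were left out, which left 23393 genes.

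Counts per library ranged from 21375407 to 48796287. Counting error is not separately stated for single genes because the spread between mice entered every test, and reads without molecular identifiers are not independent molecules.

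The main comparisons were fitted in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on age (minimum count 10, minimum total count 15), which left 15472 genes, and libraries were scaled by TMM. A quasi-likelihood model with robust estimation was fitted to all 22 libraries with 1 mean per age, so that the 4 ages shared 1 estimate of the spread. An F test of the age terms gave the any-age result, and each of the 6 pairs of ages was tested as a contrast. P-values were adjusted by Benjamini-Hochberg over the 15472 genes, with a threshold of 0.05. Every adjusted p of a single gene in the text is from this edgeR quasi-likelihood test unless another tool is named. Log2 CPM values used a prior count of 2. Levels are given as TMM-normalised CPM, mean ± SD over the libraries of an age.

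There were 29 gene lists, fixed before the data were examined together with the design, the other settings and the naming rule. They covered the circadian clock, myelin and myelinating Schwann cell, non-myelinating Schwann cell, repair Schwann cell and injury, cholesterol biosynthesis, adipocyte, lipogenesis and fatty acid synthesis, skeletal muscle, macrophage, T and NK cell, B and plasma cell, neutrophil, mast cell, MHC class II presentation, interferon response, complement, chemokines and cytokines, senescence, collagen and extracellular matrix, fibroblast, perineurial cell, endothelial and mural cell, cell cycle, heat shock, immediate early genes, nuclear oxidative phosphorylation, red blood cell, keratinocyte and skin, and neuron and axon. Older symbols were matched through RefSeq synonyms: Gm129 is Ciart, Sc4mol is Msmo1, Emr1 is Adgre1, Igj is Jchain and Beta-s is Hbb-bs. Atf3 is in both the repair Schwann cell list and the immediate early list. For each list the number of members past the threshold was counted over all genes tested and adjusted over the list alone. Each list was also compared with all other genes by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 174 pairs of list and contrast, and again with the correlation estimated for each list. With the preset correlation 76 pairs passed, and with the estimated correlation 9 passed: cholesterol biosynthesis at each old age against 5 months, the clock list in 18 against 5 months and in 21 against 18 months, adipocyte and collagen in 18 against 5 months, repair Schwann cell in 24 against 5 months, and macrophage in 24 against 18 months. The mean change of a list in log2 CPM is the mean over its members in linear fits to log2 CPM, used to compare settings, and its other medians and means are of the edgeR log2 fold changes. An adjusted p of a list is from camera with the preset correlation unless an estimated correlation is named.

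Named genes were chosen by rule. In each contrast against 5 months these were the 10 higher and 10 lower genes with the smallest p among those past the threshold with a mean log2 CPM of at least 1. Of each list, up to 4 members past the threshold were taken by size of change or, where none passed, up to 2 members with the highest mean level. Added to these were the 12 genes with the smallest any-age p among those past the threshold in the same direction at all 3 old ages, and the 5 higher and 5 lower genes with the smallest p in each contrast between old ages. Some genes that the rule names are not reported. Predicted genes (Gm numbers and Rik clones) were counted but not described. Arntl at 18 months against 5 months, Dhcr7, Cd163, Acta1 at 18 months, Malat1 and Rn45s lie outside this rule and were chosen after their values were seen. Coordinates are from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 denotes.

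The 3 contrasts against 5 months share their control libraries. The covariance and correlation of their fold changes were compared with 20 simulations of unchanged groups against the same controls, and the shared calls with those of independent lists and of 10 splits of the controls into disjoint sets of 3. Single measures of a library were compared by exact two-sided permutation tests. Relations with Rn45s were taken from deviations from the age means over the 16 libraries of the old ages, with permutation within ages. The edgeR procedure was tested on simulated counts of the 15472 genes for 24 against 5 months, with 50 genes changed at each of 4 fold sizes. It recovered 6 of 50 at 1.5-fold, 31 at 2-fold, 41 at 4-fold and 48 at 8-fold, all with the right sign, and called 5 unchanged genes. In the simulated 18 and 21 months against 5 months, which held no change, 0 genes were called.

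Other settings chosen with the design were DESeq2 1.42.0, RLE scaling, no filter, a stricter filter (10 counts in 5 libraries and mean log2 CPM of 1), the 2 excluded libraries added back, each library left out in turn, the replicate number as a block, the mean log2 CPM of the skeletal muscle or the adipocyte list as a covariate, voom with quality weights, only the 2 ages compared, and the estimated correlation for lists. Settings added after the data were seen were log2 CPM of Rn45s as a covariate, 4 libraries that stood apart left out together (18 months replicates 2 and 3, 21 months replicate 5, 24 months replicate 6), each library's trend with GC content and transcript length removed through offsets, counts thinned to an equal depth, only the genes of the authors' table, and Rn45s and Lars2 left out before scaling. Transcript GC content and length were available for 99.1% of the genes tested.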

Results

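Gene expression was measured in the sciatic nerve of mice at 4 ages, as counts per gene from poly-A selected RNA. There were 6 libraries at 5 months, the control age, 5 at 18 months, 6 at 21 months and 5 at 24 months, each from a separate mouse. Total counts per library ranged from 22105177 to 48796287 at 5 months and from 26107885 to 32748843 at 18 months. They ranged from 21375407 to 31100527 at 21 months and from 21878493 to 35434921 at 24 months. The series' title names pathways of the ageing nerve tied to age-related muscle pathology, and the comparisons ask which genes differ between the young nerve and each old age, and between the old ages.

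The libraries of the old ages differed from those of 5 months in measures of RNA content. Rn45s, the 45S precursor of ribosomal RNA, which poly-A selection should largely remove, took 0.818 ± 0.295% of the counts at 5 months (SD, n = 6), 9.25 ± 3.29% at 18 months (n = 5), 15.1 ± 6.72% at 21 months (n = 6) and 3.31 to 31.6% at 24 months (n = 5). Every old library lay above every 5-month library, and the geometric mean of Rn45s was 12.8, 19.5 and 10.1 times that at 5 months (exact two-sided permutation p = 0.00216 at each old age, the smallest possible after adjustment over 6 tests). Fewer genes were detected in the old libraries, 14262 to 15846 against 16392 to 16914 at 5 months (exact two-sided permutation, adjusted p = 0.00216 at each old age). Malat1, a nuclear non-coding RNA, stood at 227 ± 58.5 CPM at 5 months and at 1063 ± 83.4, 1462 ± 447 and 1001 ± 442 CPM at 18, 21 and 24 months before TMM scaling. The labels give no batch, so a batch that held the 5-month libraries alone and the age itself cannot be told apart in these measures. The labels also give no sex. Xist, expressed from the inactive X chromosome, stood at 363 to 846 CPM in the libraries in use, before TMM scaling. The Y-linked gene Ddx3y reached at most 0.375 CPM in all of them but 21 months replicate 5. These values point to female mice at every age.

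**Figure D1:**
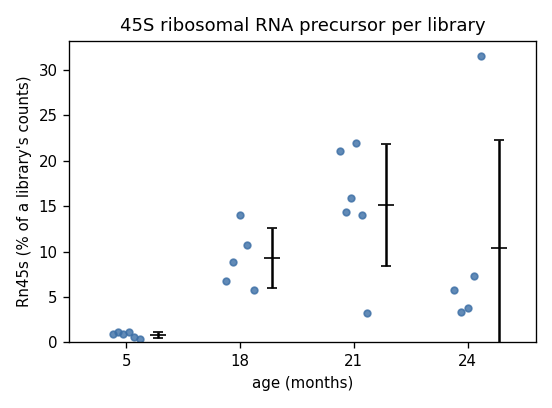
Share of each library's counts taken by Rn45s (y axis, percent) at each age (x axis, months). Points are libraries, and bars show the mean and SD, with the lower SD at 24 months ending at the axis. The 5-month libraries lie between 0.357% and 1.10%, and 24 months replicate 6 stands at 31.6%.

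Of 15472 genes tested, 1749 differed between at least some ages. Against 5 months, 103 genes were higher at all 3 old ages and 135 were lower at all 3, 238 together. These were 5 with log2 Rn45s as a covariate, chosen after the data were seen, 42 with the adipocyte covariate, 150 with the skeletal muscle covariate, 413 with voom and 157 without 5 months replicate 6. Lower cholesterol synthesis genes within the 12 genes with the smallest p included Hmgcs1, Sqle, Fdps, Sc4mol, Sc5d and Fdft1. Hmgcs1 (chromosome 13: 119690379 to 119708260, GRCm38), the first dedicated enzyme of the mevalonate pathway, fell from 916 ± 114 CPM at 5 months to 234 ± 43.9, 226 ± 15.2 and 213 ± 62.7 CPM at 18, 21 and 24 months (any-age adjusted p = 1.7e-13). The higher genes among the 12 were Abca1, a cholesterol efflux transporter, Mpeg1, a macrophage perforin, and Dbp, a clock output gene. Abca1 (chromosome 4: 53030787 to 53159895) rose from 59.6 ± 7.28 CPM to 140 ± 18.0, 200 ± 28.1 and 384 ± 136 CPM. With the Rn45s covariate 582 genes differed between ages, and with the adipocyte score as a covariate 730. Both covariates differed between 5 months and the old ages, so these lower counts do not show what made the calls.

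**Figure D2:**
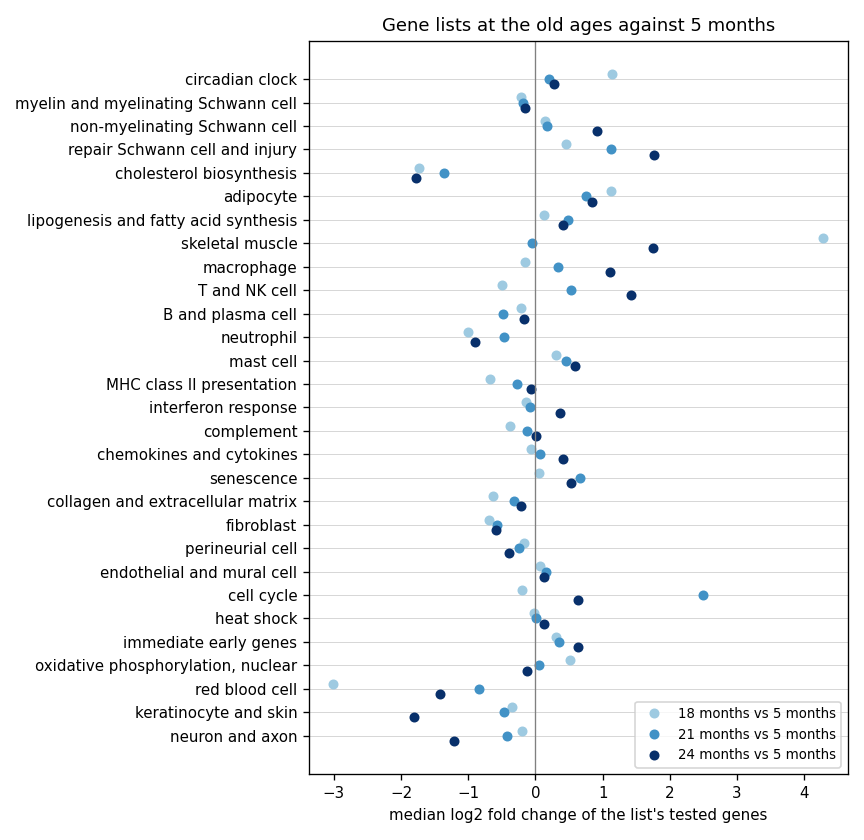
Median log2 fold change (x axis) of the tested genes of each of 29 gene lists (y axis) at 18, 21 and 24 months against 5 months. The cholesterol biosynthesis list lies at -1.73, -1.35 and -1.77, and the skeletal muscle list at 4.28, -0.04 and 1.74.

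At 18 months 18 of 19 genes in the cholesterol biosynthesis list were lower than at 5 months and 1 did not pass (19 fell adjusted over the list alone). Hmgcs1 changed by -1.97 on the log2 scale (SE 0.16, adjusted p = 4.3e-10), Sqle, squalene epoxidase, by -2.20 (SE 0.19), Mvd by -2.37 (SE 0.33) and Cyp51 by -2.13 (SE 0.26). The list's median was -1.73 (camera adjusted p = 3.7e-38; adjusted p = 0.0013 with an estimated correlation). In these comparisons Rn45s moved opposite to the list.

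In the circadian clock list at 18 months, 13 of 19 genes were higher, 2 were lower and 4 did not pass (13 and 3 adjusted over the list alone). Dbp (chromosome 7: 45705088 to 45710203) rose from 21.3 ± 5.64 to 130 ± 17.7 CPM, a log2 change of 2.61 (SE 0.21, adjusted p = 1.1e-09), and Per2, a repressor of the clock, rose by 2.55 (SE 0.32). Tef and Per3 were higher by 1.38 (SE 0.14) and 1.76 (SE 0.20). The 2 lower genes were Npas2, at -3.17 (SE 0.48, adjusted p = 5.8e-05), and Arntl, which with Clock or Npas2 activates the clock's target genes, from 38.3 ± 2.93 to 8.95 ± 3.78 CPM. The list's adjusted p was 5.2e-11 (adjusted p = 0.010 with an estimated correlation). The skeletal muscle score moved with these genes and was 8.09 ± 2.74 at 18 months against 4.54 ± 1.58 at 5 months (mean log2 CPM ± SD).

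**Figure D3:**
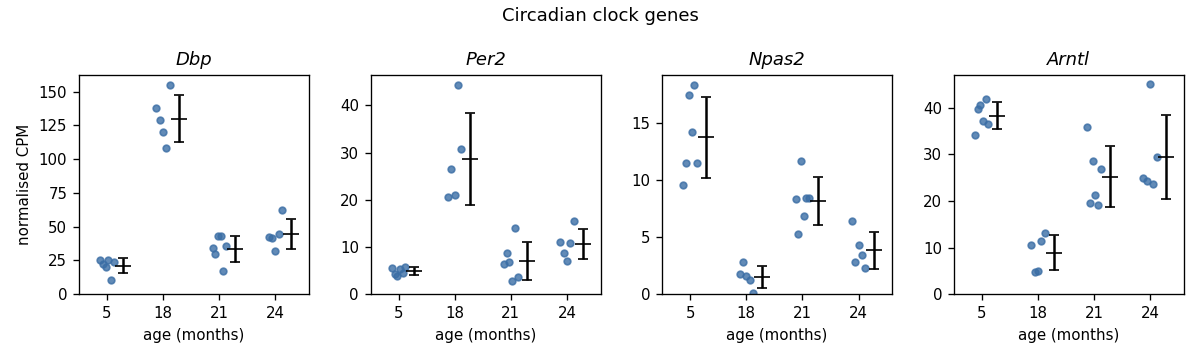
Normalised CPM (y axes) of Dbp, Per2, Npas2 and Arntl in each library at each age (x axis, months), with mean and SD. At 18 months Dbp and Per2 lie above all libraries of the other ages, and Arntl lies below them.

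In the adipocyte list 11 of 16 tested genes were higher at 18 months (14 adjusted over the list alone), and all 16 fold changes were above 0. The gene of leptin, Lep, rose by 2.86 (SE 0.52), Plin1, the fat droplet protein perilipin, by 1.52 (SE 0.20) and Adipoq by 1.44 (SE 0.22). The list's adjusted p was 5.1e-18 (adjusted p = 0.043 with an estimated correlation). In the skeletal muscle list 3 of 18 genes passed, Ttn at 6.74 (SE 1.91), Myh1 at 5.99 (SE 1.23) and Mb at 4.70 (SE 0.99), and 18 passed adjusted over the list alone (list adjusted p = 1.4e-12; adjusted p = 0.27 with an estimated correlation). Acta1, skeletal muscle actin and chosen after its values were seen, reached 3008 CPM in 18 months replicate 2 and 9121 CPM in replicate 3, against 20.3 to 722 CPM in the 5-month libraries (before TMM scaling). Moving with these, 5 of 20 nuclear oxidative phosphorylation genes were higher (13 adjusted over the list alone), among them Cox5a at 1.18 (SE 0.34) and Ndufs1 at 0.93 (SE 0.26). That list's adjusted p was 1.2e-05, and 0.44 with an estimated correlation. In log2 CPM its mean change was 0.36, without 18 months replicate 3 it was 0.13, and without the 4 libraries that stood apart it was -0.079 and the call ended.

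In the collagen and extracellular matrix list 17 of 20 genes fell at 18 months and 3 did not pass (19 fell adjusted over the list alone). Col3a1, of type III collagen, fell from 2153 ± 352 to 801 ± 116 CPM, a log2 change of -1.43 (SE 0.13, adjusted p = 6.3e-09), Col6a1 changed by -1.18 (SE 0.11) and Postn, periostin, by -1.41 (SE 0.22). The list's adjusted p was 1.7e-18 (adjusted p = 0.026 with an estimated correlation). In the fibroblast list 8 of 14 fell (10 adjusted over the list alone), with Pi16 at -1.64 (SE 0.29) and Cd34 at -0.89 (SE 0.14); its adjusted p was 1.4e-07, and 0.11 with an estimated correlation. In the myelin list 6 of 20 fell (9 adjusted over the list alone). Ugt8a, an enzyme of myelin galactolipid synthesis, changed by -1.18 (SE 0.14) and Pmp22 by -1.04 (SE 0.14). The myelin list's adjusted p was 2.2e-05, and 0.45 with an estimated correlation.

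Other groups at 18 months moved in part. In the complement list 5 of 12 genes fell (7 adjusted over the list alone), among them Serping1 at -0.71 (SE 0.15) and C1ra at -0.69 (SE 0.13). For the complement list the adjusted p was 0.0046, and 0.44 with an estimated correlation. In the MHC class II list 1 of 10 fell, H2-DMa at -0.72 (SE 0.17), and 3 adjusted over the list alone. For the MHC class II list the adjusted p was 0.0016, and 0.41 with an estimated correlation. In the macrophage list 3 of 18 were higher and 3 lower (3 and 4 adjusted over the list alone). These included Trem2 at 1.97 (SE 0.30), Gpnmb at 1.53 (SE 0.27) and Lyve1, a marker of resident tissue macrophages, at -1.41 (SE 0.41), and the list did not pass (adjusted p = 0.60). In the lipogenesis list 3 were higher and 4 lower of 16 (7 and 5 adjusted over the list alone; list adjusted p = 0.93). In the senescence list 3 were higher and 1 lower of 14 (3 and 2 adjusted over the list alone; list adjusted p = 0.51), with Cdkn2a, the p16 gene, at 1.56 (SE 0.34) and Mmp12, a macrophage elastase, at 2.58 (SE 0.52).

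In all, 870 genes differed between 18 and 5 months, 443 higher and 427 lower, of which 238 and 112 changed by at least 2-fold. Among the genes with the smallest p were also the non-coding RNAs Neat1, at 1.26 (SE 0.15), and Kcnq1ot1, at 3.04 (SE 0.38), and Col24a1, at 1.93 (SE 0.23). The count was 49 with the Rn45s covariate, which left 19 of the 72 named genes called, 98 with the adipocyte covariate, 282 with the skeletal muscle covariate, and 1391 with DESeq2. It was 578 without 18 months replicate 2, 525 without 18 months replicate 3, and 522, 495, 509 and 496 without 5 months replicates 3, 4, 5 and 6.

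At 21 months 18 of 19 genes in the cholesterol biosynthesis list were lower than at 5 months and 1 did not pass (18 adjusted over the list alone). Among them were Hmgcs1 at -2.02 (SE 0.15, adjusted p = 3.6e-11), Idi1, isopentenyl diphosphate isomerase, at -2.18 (SE 0.26) and Sc4mol at -1.82 (SE 0.17). The list's median was -1.35 (adjusted p = 2.4e-38; adjusted p = 0.0013 with an estimated correlation). In the macrophage list 6 of 18 genes rose and 1 fell (9 and 2 adjusted over the list alone). They included Trem2, a lipid receptor of macrophages, at 2.28 (SE 0.30), Gpnmb at 1.98 (SE 0.27), Ms4a7 at 1.91 (SE 0.26) and Itgax at 1.56 (SE 0.33). The list's adjusted p was 1.3e-04, and 0.43 with an estimated correlation.

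**Figure D4:**
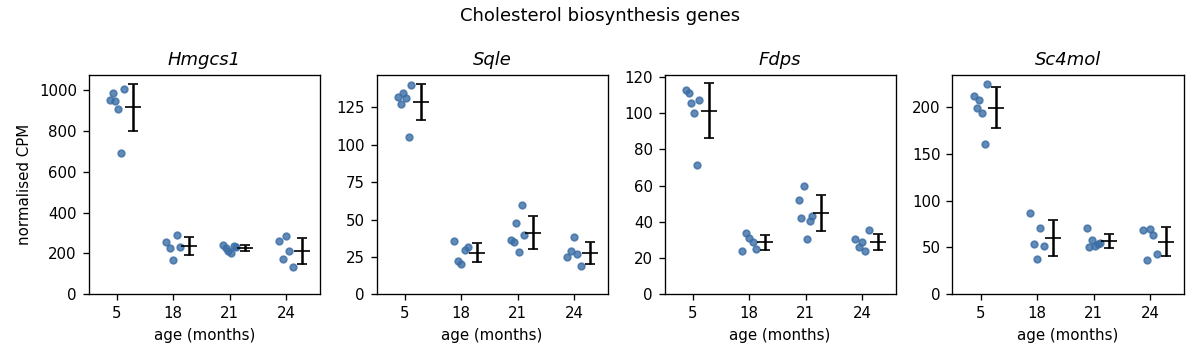
Normalised CPM (y axes) of Hmgcs1, Sqle, Fdps and Sc4mol in each library at each age (x axis, months), with mean and SD. In each panel every library of 18, 21 and 24 months lies below every library of 5 months.

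In the myelin list 6 of 20 genes fell at 21 months (8 adjusted over the list alone), with Ugt8a at -1.34 (SE 0.13, adjusted p = 2.9e-08) and Pmp2 at -1.29 (SE 0.18). For the myelin list the adjusted p was 1.1e-05, and 0.44 with an estimated correlation. In the repair Schwann cell list 2 of 14 rose (3 adjusted over the list alone), Shh, the Sonic hedgehog gene that Schwann cells express after nerve injury, at 3.0 (SE 0.46) and Jun at 0.47 (SE 0.13). For the repair Schwann cell list the adjusted p was 6.3e-05, and 0.071 with an estimated correlation. In the non-myelinating Schwann cell list 2 of 11 rose, Gfap at 1.81 (SE 0.37) and Apod at 0.80 (SE 0.15), and the list did not pass (adjusted p = 0.079). In the clock list 3 of 19 rose (3 higher and 2 lower adjusted over the list alone), Bhlhe41 at 0.78 (SE 0.16), Dbp at 0.66 (SE 0.20) and Per3 at 0.64 (SE 0.19), and the list did not pass (adjusted p = 0.29).

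In the collagen list 7 of 20 genes fell at 21 months (10 adjusted over the list alone), with Col3a1 at -0.83 (SE 0.12) and Lox, a collagen cross-linking enzyme, at -0.86 (SE 0.15). For the collagen list the adjusted p was 8.6e-09, and 0.12 with an estimated correlation. In the fibroblast list 5 of 14 fell (1 higher and 10 lower adjusted over the list alone). For the fibroblast list the adjusted p was 7.7e-05, and 0.27 with an estimated correlation. In the adipocyte list 7 of 16 rose (9 adjusted over the list alone), with Plin1 at 1.33 (SE 0.20) and Adipoq at 1.10 (SE 0.21). For the adipocyte list the adjusted p was 1.3e-10, and 0.11 with an estimated correlation. In the lipogenesis list 6 rose and 3 fell of 16 (8 and 3 adjusted over the list alone), with Pnpla3 at 1.77 (SE 0.30) and Srebf1 at 0.99 (SE 0.15) higher and Elovl6, a fatty acid elongase, at -1.02 (SE 0.14). For the lipogenesis list the adjusted p was 0.0084, and 0.44 with an estimated correlation. The senescence list passed with 3 of 14 genes higher (4 adjusted over the list alone), among them Mmp12 at 3.18 (SE 0.51). For the senescence list the adjusted p was 0.017, and 0.21 with an estimated correlation. The senescence call ended without 21 months replicate 1 (adjusted p = 0.066).

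For the skeletal muscle list at 21 months the median was -0.04 while the mean was 0.61 and the test pointed up (adjusted p = 0.0016, and 0.63 with an estimated correlation). No single gene passed, and 2 did adjusted over the list alone. In log2 CPM the mean change was 1.31, and -1.24 with the Rn45s covariate. In the cell cycle list 3 of 17 genes were higher, Top2a at 3.39 (SE 0.93), Mki67 at 2.5 (SE 0.70) and Cdc20 at 1.87 (SE 0.56), and 14 adjusted over the list alone (list adjusted p = 0.0013, and 0.45 with an estimated correlation). One library carried this: the cell cycle score of 21 months replicate 5 was 5.79, the next highest of that age was 1.68. The list's mean change in log2 CPM was 0.85, and without the 4 libraries that stood apart it was 0.11 (0.12 without 21 months replicate 5 alone, where the list's adjusted p was 0.20) and the 3 calls and the list's call ended. The endothelial and mural list passed with 1 of 16 higher (2 adjusted over the list alone), Myh11, of smooth muscle, at 0.65 (SE 0.19). For the endothelial and mural list the adjusted p was 0.035, and 0.43 with an estimated correlation. The endothelial and mural call ended without 5 months replicates 1 and 5 (adjusted p = 0.059 and 0.061) and 21 months replicates 3 and 6 (adjusted p = 0.16 and 0.065). The endothelial and mural list's mean change in log2 CPM was 0.19, and 0.12 without 21 months replicate 3. The MHC class II list passed with H2-DMa at -0.56 (SE 0.16) as its 1 lower gene of 10, also 1 adjusted over the list alone. For the MHC class II list the adjusted p was 0.029, and 0.50 with an estimated correlation. The MHC class II call ended without 21 months replicates 2 and 5 (adjusted p = 0.083 and 0.19).

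In all, 693 genes differed between 21 and 5 months, 352 higher and 341 lower, with 137 and 67 changed by at least 2-fold. The count was 5 with the Rn45s covariate, which left 4 of the 64 named genes called, 306 with the adipocyte covariate, 1042 with DESeq2, 1544 with voom and 1219 without the 4 libraries that stood apart. It was 448 without 5 months replicate 5 and 437 without 5 months replicate 6.

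At 24 months 12 of 18 genes in the macrophage list were higher than at 5 months and 1, Cd163, was lower (12 and 3 adjusted over the list alone). Gpnmb, a glycoprotein of lipid-laden macrophages (chromosome 6: 49036546 to 49070929), rose from 51.5 ± 10.1 to 631 ± 235 CPM, a log2 change of 3.62 (SE 0.29, adjusted p = 5.4e-08). Trem2 (chromosome 17: 48346401 to 48354147) rose by 3.61 (SE 0.32), Itgax by 3.23 (SE 0.36) and Cd68 by 1.86 (SE 0.18). Outside the list, Mpeg1 rose by 2.74 (SE 0.19), Ctsd, the lysosomal protease cathepsin D, by 1.98 (SE 0.18), Atp6v0d2, a subunit of the vacuolar proton pump, by 3.75 (SE 0.33) and Abca1 by 2.69 (SE 0.17). The macrophage list's median was 1.10 (adjusted p = 9.3e-13, and adjusted p = 0.10 with an estimated correlation).

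**Figure D5:**
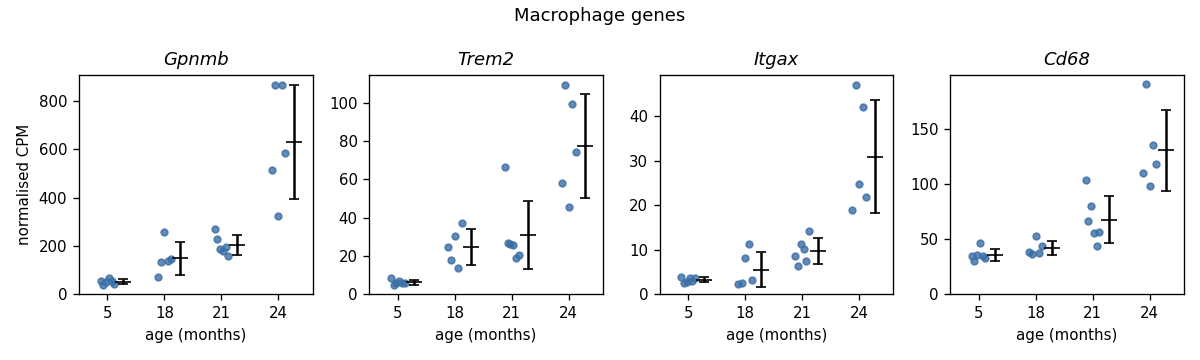
Normalised CPM (y axes) of Gpnmb, Trem2, Itgax and Cd68 in each library at each age (x axis, months), with mean and SD. In the Gpnmb panel the 24-month mean is 631 CPM and the 5-month mean 51.5 CPM.

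In the interferon response list 3 of 19 genes rose at 24 months (5 adjusted over the list alone), with Bst2 at 0.86 (SE 0.22) and Ifit3 at 0.94 (SE 0.19), and all 19 fold changes were above 0 (adjusted p = 0.0018, and 0.43 with an estimated correlation). The interferon response list's mean change in log2 CPM was 0.27, and 0.16, 0.18 and 0.45 without 24 months replicates 3, 5 and 6. In the complement list 2 rose and 2 fell of 12 (2 and 3 adjusted over the list alone; list adjusted p = 0.29), with C3ar1, the receptor of the C3a fragment, at 1.73 (SE 0.17) and Cfp at -1.0 (SE 0.29). In the chemokine list Cxcl10 at 2.77 (SE 0.45) and Ccl8 at 2.18 (SE 0.45) were the 2 higher of 16 (4 and 2 lower adjusted over the list alone; list adjusted p = 0.29). Jchain, of plasma cells, listed as Igj, at 4.10 (SE 1.05) and Cd22 at 3.03 (SE 0.70) were the 2 higher of 9 B and plasma cell genes. The neutrophil gene Csf3r was the 1 of 5 higher, at 1.64 (SE 0.34), with list adjusted p = 0.69 and 0.83. The MHC class II list had 2 of 10 lower and did not pass (adjusted p = 0.29). The T and NK cell list had no gene of 12 past the threshold, with Il2rb at 1.88 (SE 1.0) (adjusted p = 0.60). The mast cell list passed upward (adjusted p = 0.027, and 0.45 with an estimated correlation) with no single gene of 10 past the threshold and 1 adjusted over the list alone, and its mean change in log2 CPM was 0.48, and -0.82 with the adipocyte covariate, 0.30 without 24 months replicate 5 and 0.29 without 5 months replicate 2. The mast cell call ended without 5 months replicates 1 and 2 (adjusted p = 0.055 and 0.089) and 24 months replicate 5 (adjusted p = 0.086).

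In the repair Schwann cell list 6 of 14 genes rose at 24 months (6 adjusted over the list alone), with Shh at 3.81 (SE 0.49, adjusted p = 4.2e-05), Btc, betacellulin, at 2.82 (SE 0.65), Runx2 at 1.78 (SE 0.44) and Sox2 at 0.99 (SE 0.27). For the repair Schwann cell list the adjusted p was 1.4e-07, and 0.019 with an estimated correlation. In the non-myelinating Schwann cell list 6 of 11 rose, also 6 adjusted over the list alone with 1 lower, among them Gfap, with a log2 change of 3.18 (SE 0.40, adjusted p = 9.2e-07), L1cam at 1.09 (SE 0.17) and Apod at 1.25 (SE 0.16). For the non-myelinating Schwann cell list the adjusted p was 2.2e-05, and 0.071 with an estimated correlation. In the neuron and axon list 6 of 11 fell and 1 rose (the same numbers adjusted over the list alone). The heavy and medium neurofilament genes Nefh and Nefm changed by -2.5 (SE 0.41) and -1.71 (SE 0.34), and Snap25, of the synaptic vesicle fusion machinery, by -1.66 (SE 0.35), while Tubb3 rose by 1.73 (SE 0.35). That list's adjusted p was 7.1e-05, and 0.13 with an estimated correlation. Neuronal cell bodies lie outside the sciatic nerve. In the myelin list 7 of 20 fell (8 adjusted over the list alone), with Ugt8a at -1.16 (SE 0.14). For the myelin list the adjusted p was 0.0013, and 0.57 with an estimated correlation.

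In the cholesterol biosynthesis list 18 of 19 genes fell at 24 months and Dhcr7 did not pass (19 adjusted over the list alone), with Idi1 at -2.54 (SE 0.28) and Sqle at -2.21 (SE 0.19). The list's median was -1.77 (adjusted p = 2.4e-38; adjusted p = 0.0013 with an estimated correlation). In the lipogenesis list 5 rose and 2 fell of 16 (6 and 2 adjusted over the list alone), with Pnpla3 at 1.83 (SE 0.31) and Srebf1, the regulator of fatty acid synthesis, at 1.22 (SE 0.15) higher and Elovl6 at -1.16 (SE 0.15). For the lipogenesis list the adjusted p was 0.0056, and 0.43 with an estimated correlation. In the adipocyte list 8 of 16 rose (13 adjusted over the list alone), with Lep at 2.59 (SE 0.51) and Plin1 at 1.43 (SE 0.20). For the adipocyte list the adjusted p was 1.9e-12, and 0.083 with an estimated correlation. The skeletal muscle list had 1 of 18 higher, Myh2 at 4.07 (SE 1.11), and 2 adjusted over the list alone (list adjusted p = 0.019, and 0.72 with an estimated correlation), and its mean change in log2 CPM was 1.19, and -0.79 with the Rn45s covariate, where the call ended. Replicates 1 and 6 carried this rise: the skeletal muscle scores of the 24-month libraries were 8.70, 5.06, 4.49, 1.91 and 8.50, and the mean change was 0.45, 2.15 and 0.50 without 24 months replicates 1, 5 and 6. The skeletal muscle call ended without 5 months replicate 3 (adjusted p = 0.096) and 24 months replicates 1 and 6 (adjusted p = 0.31 and 0.24).

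In the senescence list 5 of 14 rose and 1 fell (7 and 2 adjusted over the list alone), with Mmp12 at 5.17 (SE 0.56), Cdkn2a at 2.09 (SE 0.35) and Timp1 at 1.64 (SE 0.40), and Mmp3 at -1.28 (SE 0.36). That list's adjusted p was 6.1e-04, and 0.071 with an estimated correlation. In the collagen list 6 of 20 fell (7 adjusted over the list alone), with Lox at -1.07 (SE 0.16). For the collagen list the adjusted p was 0.0059, and 0.45 with an estimated correlation. The collagen call ended without 24 months replicate 3 (adjusted p = 0.085). In the fibroblast list 8 of 14 fell (8 lower and 1 higher adjusted over the list alone), with Pi16 at -1.99 (SE 0.29) and Clec3b at -1.54 (SE 0.30). For the fibroblast list the adjusted p was 7.7e-06, and 0.21 with an estimated correlation. In the clock list 5 rose and 1 fell of 19 (6 and 1 adjusted over the list alone), with Bhlhe41 at 1.40 (SE 0.17) and Npas2 at -1.83 (SE 0.45). For the clock list the adjusted p was 0.0059, and 0.28 with an estimated correlation. In the perineurial cell list 2 rose and 3 fell of 11 (2 and 6 adjusted over the list alone; list adjusted p = 0.091), with Itgb8 at 0.84 (SE 0.15) higher and Lypd2 at -1.25 (SE 0.21) and the tight junction gene Cldn1 at -0.72 (SE 0.16) lower. In the heat shock, red blood cell and keratinocyte lists no gene passed, with list adjusted p = 0.17, 0.33 and 0.12. In the immediate early list 4 of 15 rose, also 4 adjusted over the list alone, with Arc at 2.21 (SE 0.66) and Fos at 1.07 (SE 0.33). For the immediate early list the adjusted p was 0.014, and 0.39 with an estimated correlation. The immediate early call ended without 24 months replicate 6 (adjusted p = 0.061). The immediate early list's mean change in log2 CPM was 0.35, and 0.21 without 24 months replicate 6.

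In all, 1112 genes differed between 24 and 5 months, 613 higher and 499 lower, with 267 and 127 changed by at least 2-fold. The count was 198 with the Rn45s covariate, which left 40 of the 88 named genes called, 266 with the adipocyte covariate, 2551 with voom and 2775 in a fit of the 2 ages alone. Of 76 ribosomal protein genes, a group counted after the data were seen, 30 were lower at 24 months and none was higher (median log2 fold change -0.35, and -0.24 with GC content and length removed).

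Some genes were called against 5 months at more than 1 old age. The same direction was shared by 122 higher and 166 lower genes at 18 and 21 months, 148 and 202 at 18 and 24 months, and 225 and 214 at 21 and 24 months. Another 3 genes were called in opposite directions at 18 and 24 months. Independent lists would share 10.1 and 9.41, 17.6 and 13.8, and 13.9 and 11 genes. In simulated counts 0, 0 and 5 unchanged genes were called at 18, 21 and 24 months, so a simulated count of shared calls was bound to be near 0 and says nothing here. The shared totals of 288, 350 and 439 genes were 5, 26 and 5 with the Rn45s covariate, 64, 51 and 139 with the adipocyte covariate, and 507, 569 and 952 with voom. At 18 and 21 months and at 18 and 24 months they were 170 and 194 with the skeletal muscle covariate and 188 and 231 without 5 months replicate 6, and at 18 and 24 months 643 in a fit of the 2 ages. With disjoint sets of 3 controls the counts averaged 31.3 and 62.9, 47.0 and 79.9, and 55.3 and 78.6. The covariance of log2 fold changes was 0.230, 0.369 and 0.347 against 0.228, 0.226 and 0.224 for simulated unchanged groups with the same controls. At 18 and 21 months it was 0.0026 above the simulated value. With disjoint sets of 3 controls, where shared control libraries add no covariance, it was 0.209, 0.354 and 0.320. For 18 and 21 months 0.209 remained with disjoint controls, which argues against noise of the shared control libraries as the main source of the 0.230. The simulation gave all ages the same spread of a gene. It can therefore misstate the noise of the 5-month libraries, and its 0.228 does not decide the question. A difference common to all 5-month libraries, such as a batch, would remain with disjoint sets. The correlation across genes, which are not independent replicates, was 0.26, 0.38 and 0.45, and 0.22, 0.33 and 0.37 with disjoint sets of 3 controls. In the simulation it was 0.47, 0.44 and 0.47. The simulated groups held no change, so that correlation came from the shared controls alone. It does not show that the old ages were less alike than unchanged groups.

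Between 18 and 21 months 11 of 19 clock genes were lower at 21 than at 18 months and 2 were higher (13 and 2 adjusted over the list alone), with Dbp at -1.95 (SE 0.21, adjusted p = 2.7e-06), Tef at -1.17 (SE 0.13) and Nr1d2 at -1.27 (SE 0.16) lower. Higher were Arntl (chromosome 7: 113207465 to 113314126) at 1.49 (SE 0.24) and Npas2 (chromosome 1: 39193731 to 39363236) at 2.42 (SE 0.47). The list's adjusted p was 6.6e-11 (adjusted p = 0.010 with an estimated correlation). Fkbp5, a glucocorticoid-induced gene, changed by -1.57 (SE 0.21). The lipogenic genes Acly, Acaca and Fasn were higher by 1.39 (SE 0.24), 0.82 (SE 0.15) and 1.47 (SE 0.30) as the 3 called of 16 (5 and 1 lower adjusted over the list alone; list adjusted p = 0.0036, and adjusted p = 0.41 with an estimated correlation). Cx3cr1, the fractalkine receptor of macrophages, was 1 of 18 macrophage genes higher, at 1.0 (SE 0.21), and 11 passed adjusted over the list alone (list adjusted p = 1.8e-07, and 0.27 with an estimated correlation). Further lists passed as sets with at most 1 gene past the threshold. The collagen list moved up as a set, with a median of 0.29 (adjusted p = 3.2e-06, and 0.25 with an estimated correlation). The complement list moved up as a set, with a median of 0.32 (adjusted p = 0.012, and 0.46 with an estimated correlation). The complement call ended without 18 months replicate 3 (adjusted p = 0.067) and 21 months replicate 6 (adjusted p = 0.056). The repair Schwann cell list moved up as a set, with a median of 0.64 (adjusted p = 0.035, and 0.37 with an estimated correlation). The repair Schwann cell call ended without 18 months replicates 2, 3 and 6 (adjusted p = 0.12, 0.053 and 0.079) and 21 months replicates 2, 5 and 6 (adjusted p = 0.11, 0.073 and 0.070). The fibroblast list moved up as a set, with a median of 0.21 (adjusted p = 0.047, and 0.54 with an estimated correlation). The fibroblast call ended without 18 months replicates 1, 3 and 4 (adjusted p = 0.052, 0.085 and 0.15), 21 months replicates 1, 3 and 6 (adjusted p = 0.21, 0.11 and 0.21) and 24 months replicates 5 and 6 (adjusted p = 0.051 and 0.052). The cell cycle list moved up as a set, with a median of 3.10 (adjusted p = 1.6e-05, and 0.37 with an estimated correlation). The cell cycle list's mean change in log2 CPM was 1.64, and 0.90 without 21 months replicate 5, where the call held (adjusted p = 0.012). The skeletal muscle list moved down as a set, with a median of -4.21 (adjusted p = 5.8e-06, and 0.45 with an estimated correlation). The skeletal muscle list's mean change in log2 CPM was -2.25, and -1.38 without 18 months replicate 3. The oxidative phosphorylation list moved down as a set, with a median of -0.38 (adjusted p = 2.4e-04, and 0.50 with an estimated correlation). The oxidative phosphorylation call ended without 18 months replicate 3 (adjusted p = 0.21). The oxidative phosphorylation list's mean change in log2 CPM was -0.31, and -0.08 without 18 months replicate 3. The adipocyte list moved down as a set, with a median of -0.36 (adjusted p = 4.3e-04, and 0.43 with an estimated correlation). Adjusted over the list alone, 8 collagen genes rose, 16 muscle and 5 oxidative phosphorylation genes fell, and 14 cell cycle genes rose. Without the 4 libraries that stood apart the mean change in log2 CPM of the oxidative phosphorylation list was 0.17, against -0.31 with them, and the calls of the skeletal muscle, adipocyte and repair Schwann cell lists ended. In all, 182 genes differed, 89 higher and 93 lower at 21 months. The count was 923 with DESeq2, 9 with voom, 62 with the skeletal muscle covariate, 39 with the adipocyte covariate and 14 in a fit of the 2 ages. It was 56, 117, 376 and 337 without 18 months replicates 2, 3, 4 and 6, 98 and 112 without 21 months replicates 1 and 3, and 120, 116, 120 and 121 without 5 months replicates 2, 3, 5 and 6.

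Between 21 and 24 months 7 of 18 genes in the macrophage list rose (12 and 1 lower adjusted over the list alone), with Itgax at 1.67 (SE 0.34), Gpnmb at 1.63 (SE 0.27) and Clec7a at 1.25 (SE 0.24). For the macrophage list the adjusted p was 1.9e-12, and 0.11 with an estimated correlation. In the non-myelinating Schwann cell list 3 of 11 rose, Ngfr, the low-affinity neurotrophin receptor, at 0.80 (SE 0.18), L1cam at 0.72 (SE 0.17) and Chl1 at 0.57 (SE 0.13), and 6 adjusted over the list alone (list adjusted p = 4.4e-05, and 0.079 with an estimated correlation). Cybb, of the phagocyte oxidase, rose by 1.09 (SE 0.17) and Syt4 by 1.82 (SE 0.26), while Cdkn1c changed by -1.15 (SE 0.18) and the ribosomal protein gene Rps13 by -0.54 (SE 0.11). In the cholesterol list no gene of 19 passed and 4 fell adjusted over the list alone, with Hmgcs1 at -0.09 (SE 0.15). For the cholesterol list the adjusted p was 9.1e-05, and 0.36 with an estimated correlation. The interferon response list moved up as a set, with a median of 0.53 (adjusted p = 6.5e-05, and 0.30 with an estimated correlation). The complement list moved up as a set, with a median of 0.13 (adjusted p = 0.0035, and 0.44 with an estimated correlation). The complement call ended without 21 months replicate 5 (adjusted p = 0.27). The repair Schwann cell list moved up as a set, with a median of 0.47 (adjusted p = 0.0079, and 0.25 with an estimated correlation). The collagen list moved up as a set, with a median of 0.22 (adjusted p = 0.0049, and 0.45 with an estimated correlation). The collagen call ended without 21 months replicate 5 (adjusted p = 0.074). The collagen list's mean change in log2 CPM was 0.09, and 0.05 without 21 months replicate 4 and 0.05 and 0.18 without 24 months replicates 2 and 3. The clock list moved up as a set, with a median of 0.22 (adjusted p = 0.014, and 0.37 with an estimated correlation). The clock call ended without 21 months replicate 5 (adjusted p = 0.13) and 24 months replicate 6 (adjusted p = 0.081). The senescence list moved up as a set, with a median of 0.26 (adjusted p = 0.038, and 0.27 with an estimated correlation). The senescence call ended without 21 months replicates 4 and 5 (adjusted p = 0.095 and 0.13) and 24 months replicates 2, 5 and 6 (adjusted p = 0.12, 0.065 and 0.050). The neuron and axon list moved down as a set, with a median of -0.72 (adjusted p = 6.7e-04, and 0.23 with an estimated correlation). The oxidative phosphorylation list moved down as a set, with a median of -0.19 (adjusted p = 0.02, and 0.70 with an estimated correlation). The oxidative phosphorylation call ended without 21 months replicates 1, 4 and 6 (adjusted p = 0.096, 0.062 and 0.054) and 24 months replicates 3 and 5 (adjusted p = 0.096 and 0.056). In all, 75 genes differed, 63 higher and 12 lower. The count was 285 with DESeq2, 45 with the Rn45s covariate, 34 with the adipocyte covariate, 27 in a fit of the 2 ages and 290 without the 4 libraries that stood apart. It was 48 and 143 without 21 months replicates 4 and 5, and 16 and 37 without 24 months replicates 2 and 5.

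From 18 to 24 months 14 of 18 genes in the macrophage list rose (15 adjusted over the list alone). Cx3cr1 rose from 20.3 ± 5.85 to 79.0 ± 13.6 CPM, a log2 change of 1.96 (SE 0.22, adjusted p = 1.9e-06), Itgax by 2.5 (SE 0.38) and Gpnmb by 2.08 (SE 0.29). For the macrophage list the adjusted p was 3.8e-20, and 0.044 with an estimated correlation. In the complement list 5 of 12 rose, also 5 adjusted over the list alone, with C3ar1 at 1.61 (SE 0.18) and C5ar1 at 1.41 (SE 0.29). For the complement list the adjusted p was 1.9e-05, and 0.27 with an estimated correlation. In the collagen list 9 of 20 rose (15 adjusted over the list alone), with Thbs2 at 0.87 (SE 0.16) and Col3a1 at 0.72 (SE 0.13). For the collagen list the adjusted p was 4.3e-10, and 0.10 with an estimated correlation. In the clock list 7 fell and 1, Arntl, rose (10 and 2 adjusted over the list alone), with Dbp at -1.54 (SE 0.22). For the clock list the adjusted p was 8.5e-06, and 0.071 with an estimated correlation. In the neuron and axon list 3 fell and 1 rose of 11 (6 and 1 adjusted over the list alone), with Snap25 at -1.61 (SE 0.36). For the neuron and axon list the adjusted p was 4.6e-04, and 0.21 with an estimated correlation. Non-myelinating Schwann cell genes rose in 5 of 11 cases, with Gfap at 2.21 (SE 0.41), and the lipogenesis list had 4 of 16 higher, with Fasn at 1.52 (SE 0.30) (list adjusted p = 1.5e-04 and 0.0013, and 0.10 and 0.37 with an estimated correlation). The repair Schwann cell list moved up as a set, with a median of 0.96 (adjusted p = 3.3e-05, and 0.071 with an estimated correlation). The interferon response list moved up as a set, with a median of 0.58 (adjusted p = 5.0e-05, and 0.29 with an estimated correlation). The chemokines list moved up as a set, with a median of 0.75 (adjusted p = 0.0066, and 0.11 with an estimated correlation). The senescence list moved up as a set, with a median of 0.52 (adjusted p = 0.0013, and 0.079 with an estimated correlation). The T and NK cell list moved up as a set, with a median of 1.43 (adjusted p = 0.047, and 0.41 with an estimated correlation). The T and NK cell score of 24 months replicate 3 was 1.95 and the next highest of that age 0.013. The T and NK cell call ended without 18 months replicates 2, 3 and 6 (adjusted p = 0.087, 0.053 and 0.080), 21 months replicates 1, 5 and 6 (adjusted p = 0.055, 0.063 and 0.059) and 24 months replicates 3 and 5 (adjusted p = 0.30 and 0.072). The T and NK cell list's mean change in log2 CPM was 1.42, and 0.86 without 24 months replicate 3. The cell cycle list moved up as a set, with a median of 1.15 (adjusted p = 0.0066, and 0.51 with an estimated correlation). The skeletal muscle list moved down as a set, with a median of -2.59 (adjusted p = 4.8e-06, and 0.45 with an estimated correlation). The skeletal muscle list's mean change in log2 CPM was -2.36, and -1.50 without 18 months replicate 3 and -1.41 without 24 months replicate 5. The oxidative phosphorylation list moved down as a set, with a median of -0.58 (adjusted p = 1.4e-07, and 0.39 with an estimated correlation). The oxidative phosphorylation list's mean change in log2 CPM was -0.48, and -0.25 without 18 months replicate 3. In all, 489 genes differed, 376 higher and 113 lower, with 945 by DESeq2, 281 by voom, 288 with the skeletal muscle covariate and 297 in a fit of the 2 ages. The count was 308 without 18 months replicate 2, and 297 and 321 without 24 months replicates 2 and 5.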

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

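The tests of fewer myelinating Schwann cells, of the time of day, of a progressive change with age and of the 4 libraries that stood apart were chosen only after the result was seen.

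Several libraries lay far from the others of their age, by the gap of the highest or lowest value relative to the range of the group. Of 155 groups tested 20 had such a library. For normally distributed values chance gives about 1 in 20 groups. The CPM values and percentages were tested without a log scale, and Hbb-bs, with its wide spread, was flagged at every age. The chance rate for these measures is therefore not known. The library of 21 months replicate 1 had the lowest total of its age, 21375407 counts, and 8372 CPM of the hemoglobin beta gene Hbb-bs. In 24 months replicate 6, Rn45s took 31.6% and Lars2 3.71% of the counts, Hbb-bs reached 4670 CPM and the red blood cell score 6.89. Hbb-bs was also far above the rest of the age in 5 months replicate 5, at 20591 CPM, and in 18 months replicate 2, at 2160 CPM. In 5 months replicate 1, Acta1 stood at 722 CPM, the non-myelinating Schwann cell score at 5.84 and the repair Schwann cell score at 1.49. The cholesterol score of 5 months replicate 5 was the lowest of its age at 6.04, and its interferon score the highest at 4.41. The interferon score of 18 months replicate 6 was 3.83, the perineurial score of 18 months replicate 3 was 5.59 and the keratinocyte score of 5 months replicate 6 was 1.93.

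In 21 months replicate 5 the Y-linked gene Ddx3y reached 27.1 CPM against at most 0.375 CPM in the others of its age. Of its age, the same library had the lowest myelin score, 8.72, the lowest complement score, 5.85, and the highest cell cycle score, 5.79.

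The 2 libraries excluded by the study carried signal above the 5-month level, as the other old libraries did for Rn45s. Rn45s took 4.84% of the counts in 18 months replicate 5 and 4.95% in 24 months replicate 4, against at most 1.10% at 5 months. The libraries in use held 5.81 to 14.1% at 18 months and 3.31 to 31.6% at 24 months. Ddx3y stood at 0.212 and 5.09 CPM in the excluded libraries, against 0 at 5 months. In the libraries in use it reached at most 0.150 CPM at 18 months and 0.141 CPM at 24 months.

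The old ages differed among themselves in the test of the difference itself. In 182 genes the change since 5 months differed between 21 and 18 months, in 75 between 24 and 21 months and in 489 between 24 and 18 months. The median of the clock list was -0.84 in 21 against 18 months, and that of the macrophage list was 1.27 in 24 against 18 months.

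Random regrouping was set against each count. In every comparison 1 of 50 splits, the real one, gave as many genes. The highest other split gave 0 genes against the real 870 for 18 and 5 months, 4 against 693 for 21 and 5 months, 1 against 1112 for 24 and 5 months, 4 against 75 for 24 and 21 months and 1 against 1749 for any age. For 21 and 18 months the highest other split gave 111 genes against 182, and it moved only 21 months replicate 6. For 24 and 18 months it gave 238 against 489, and it parted the libraries by skeletal muscle score, at a mean of 9.31 against 4.50, a gap as large in 0.794% of splits, which points to a structure in muscle content. Fewer than 0.05 of the splits reached the real counts, which argues against a chance division of the libraries, although 50 splits can show no less than 1 in 50. Splits that mix differing ages also raise the estimated spread and so lower their own counts. The sizes of the counts are not settled by this. With 1 library left out they ran from 56 to 376 for 21 and 18 months and from 16 to 143 for 24 and 21 months.

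Of 19 cholesterol genes 18 were lower at each old age. The slope of the list on Rn45s within the old ages predicted a change of -0.31, where -1.66 was observed. The 95% interval of the slope gave -0.74 to 0.12, which argues against ribosomal RNA carry-over as the whole cause. In 24 against 5 months, removing the trends with GC content and length kept 98.9% of the median. The cholesterol list fell by 1.49 more than the myelin list (-1.49, 95% bootstrap interval over libraries -1.70 to -1.26). At 24 months this argues against fewer myelinating Schwann cells alone, and these 2 tests were not run for 18 and 21 months. A batch that held the 5-month libraries alone and age, a biological difference that was not tested, cannot be told apart by these data.

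The clock genes differed at 18 months. Of 11 clock genes 10 were called at 18 months with the 2 arms of the clock in opposite directions, which is consistent with a different time of day of collection at 18 months, a hypothesis since the labels give no time. At 24 months the mean size of the changes was 37.9% of that at 18 months, and 6 genes differed between those ages, which argues against a steady change with age. In the whole clock list 15 genes were called at 18 months. Without the 4 libraries that stood apart 14 of these 15 (93.3%) stayed called, which argues against muscle in 18 months replicates 2 and 3. With the skeletal muscle score as a covariate 11 of the 15 (73.3%) stayed called. Muscle in the nerves as a whole and a change specific to 18 months therefore stay open.

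Of 18 macrophage genes 12 were higher and 1 was lower at 24 months. The slope on Rn45s predicted -0.050, with -0.60 to 0.50 from the 95% interval of the slope, where 1.18 was observed. Removing GC content and length trends left 107% of the median. These values argue against ribosomal RNA carry-over and against GC content and length as the cause. The smallest difference between the change of the macrophage list and that of another cell type's list was 0.70, for the mast cell list. Its 95% bootstrap interval over libraries was 0.16 to 1.21, and with so few libraries such an interval can be too narrow. This argues against a lower share of Schwann cells alone, since that would raise all other types alike. Age and a batch of the 5-month libraries stay open, although the rise between 18 and 24 months does not involve 5 months. More macrophages and higher expression per macrophage were not separated.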

How the results depend on the processing

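The tests with the Rn45s covariate and without the 4 libraries that stood apart were chosen only after the result was seen. None of the named genes reversed in any setting, and the cause was not tested for any change below unless stated. Other settings left the counts within 1.5 times. A list has no value under its own score as a covariate.

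With DESeq2 the counts were 2637 for any age, 1391 and 1042 at 18 and 21 months against 5 months, 923 for 21 and 18 months, 285 for 24 and 21 months and 945 for 24 and 18 months. With voom and quality weights they were 3467 for any age, 1544 and 2551 at 21 and 24 months against 5 months, 9 for 21 and 18 months and 281 for 24 and 18 months, and the overlaps of the old ages were 507, 569 and 952 genes, with 413 in all 3. With only the 2 ages compared, which leaves fewer libraries, the counts were 2775 for 24 and 5 months, 14 for 21 and 18 months, 27 for 24 and 21 months and 297 for 24 and 18 months, with 643 shared by 18 and 24 months.

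With the Rn45s covariate the counts were 582 for any age, 49, 5 and 198 at 18, 21 and 24 months against 5 months and 45 for 24 and 21 months, and the overlaps were 5, 26 and 5, with 5 in all 3. Rn45s separates 5 months from the old ages, so this covariate overlaps with age. The skeletal muscle list then had a mean of -1.24 at 21 months and -0.79 at 24 months against 5 months. With the adipocyte covariate the counts were 730 for any age, 98, 306 and 266 against 5 months, 39 for 21 and 18 months and 34 for 24 and 21 months, with overlaps of 64, 51 and 139 and 42 in all 3, and the mast cell list had a mean of -0.82 at 24 months. The adipocyte score was at most 5.68 at 5 months and at least 6.05 at 18 months and 6.06 at 24 months. It was 5.56 to 6.42 at 21 months. This covariate thus also overlaps with age, and the lower counts do not show that fat content made the calls. With the skeletal muscle covariate the counts were 282 for 18 and 5 months, 62 for 21 and 18 months and 288 for 24 and 18 months, with 170 shared by 18 and 21 months and 194 by 18 and 24 months and 150 by all 3. Without the 4 libraries that stood apart they were 1219 for 21 and 5 months and 290 for 24 and 21 months, and the oxidative phosphorylation list had a mean of -0.079 in 18 against 5 months and 0.17 in 21 against 18 months.

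With the replicate number as a block the counts were 1153 for any age, 563 for 18 and 5 months, 69 for 21 and 18 months and 33 for 24 and 21 months. The numbers did not pair the libraries: same-numbered libraries had a mean correlation of -0.012 over 30 pairs, others 0.0028 over 151, and 1 of 22 libraries correlated best with its own number. The block left 75 of 76 list calls.

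With an estimated correlation 9 of the 76 list calls held. Of the list calls, 61 of 76 held with the Rn45s covariate, 59 of 72 with the adipocyte covariate, 62 of 71 with the skeletal muscle covariate and 60 of 76 without the 4 libraries.

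Leaving out 1 library gave 1231 to 2201 genes for any age, 495 to 1177, 437 to 857 and 812 to 1510 at 18, 21 and 24 months against 5 months, 56 to 376 for 21 and 18 months, 16 to 143 for 24 and 21 months and 297 to 713 for 24 and 18 months. The overlaps were 188 to 353, 231 to 497 and 296 to 531, with 157 to 297 in all 3, and the list calls 71 to 79. The lowest were without 5 months replicate 6 (1231, 437, 188, 231 and 157), 5 months replicate 4 (495), 24 months replicate 6 (812), 18 months replicate 2 (56) and 24 months replicate 2 (16 and 297). Without 21 months replicate 5 the counts were the highest for any age (2201) and for 18 and 24 months against 5 months (1177 and 1510). They were also the highest for 24 and 21 months (143) and for 24 and 18 months (713).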

Other observations

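The test of genes that stood apart in 1 library was chosen only after the result was seen.

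At 24 months against 5 months, genes outside the lists that rose with the smallest p included Tnc, the matrix protein tenascin C, by 2.32 (SE 0.24), and Adam11, a membrane protein of neural tissue, by 2.25 (SE 0.21). At 21 months against 5 months Ppp2r2c, a regulatory subunit of protein phosphatase, rose by 2.41 (SE 0.29) and Rap1gap, which inactivates Rap1, by 1.48 (SE 0.19). Of 76 ribosomal protein genes, a group chosen after the data were seen, 10 were lower at 18 months against 5 months, 4 were higher and 2 lower at 21 months, and 7 were lower in 24 against 21 months.

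The library of 21 months replicate 5 held 206 genes at over 4 times the level of the highest other library, against at most 59 such genes in any other library. Among them were Hbb-y and Hba-x, embryonic hemoglobin genes, at 854 and 344 CPM against at most 4.74 and 4.40 CPM elsewhere. Sox11 stood at 79.0 CPM, Hmga2 at 266 CPM, Myh7 at 148 CPM and Top2a at 233 CPM, the last against at most 15.2 CPM. These genes were chosen after their values were seen. The Y-linked genes Eif2s3y, Kdm5d and Uty reached 14.6, 17.6 and 7.35 CPM there, beside 424 CPM of Xist, which is expressed from the inactive X chromosome. This library may hold RNA of another sample. Its myelin score of 8.72, against 8.82 in 18 months replicate 3, argues against a library without nerve RNA. The embryonic hemoglobin and Y-linked genes point to RNA of an embryonic source that included male cells. Which sample it came from, and whether the nerve was adult, these values do not tell. The library was kept in each 21-month mean and count. Without it 767 genes differed between 21 and 5 months in place of 693, 240 between 21 and 18 months in place of 182, and 143 between 24 and 21 months in place of 75. All ages shared 1 estimate of the spread, and contrasts without 21 months rose too. They gave 1177 genes in place of 870 for 18 and 5 months, and 1510 in place of 1112 for 24 and 5 months. For 24 and 18 months the count was 713 in place of 489.

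Within the 16 libraries of the old ages, deviations from the age means of Rn45s were compared with 5 measures. For Lars2 Pearson's r was 0.988 (permutation p = 5.0e-05, adjusted p = 2.5e-04) and Spearman's rho 0.944 (adjusted p = 2.5e-04), and r was 0.966 without the 2 libraries farthest from the median. For Malat1 r was 0.872 (permutation, adjusted p = 5.0e-04) and rho 0.865 (adjusted p = 2.5e-04), and r was 0.738 without 2 libraries. For the cholesterol list r was -0.41 and rho -0.45 (permutation p = 0.16 and 0.099, adjusted p = 0.27 and 0.16). The macrophage and ribosomal protein scores had r of -0.06 and 0.17 (permutation p = 0.84 and 0.51).

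Across 12483 genes, which are not independent replicates, log2 fold changes against 5 months had a Spearman correlation with GC content of 0.12, 0.35 and 0.25 at 18, 21 and 24 months, and with transcript length of 0.07, 0.06 and 0.18.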
